A study of Mus musculus with 22 samples.

How the data were processed

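RNA from urogenital sinus epithelium of 22 samples of mouse fetuses at embryonic day E16.75 was profiled, in 4 groups by sex and genotype. Per the labels' protocols, the sinus was digested with trypsin and collagenase, the mesenchyme was separated under a microscope, the bladder and urethral epithelium was removed, and total RNA was labelled with biotin for Affymetrix whole-transcript arrays. The authors deposited 1 table of log2 values, with 72688 probe sets on each of the 22 arrays, of which 65770 were transcript clusters and 6918 were control probe sets. That the scale is log2 was read from the values, which ran from 1.59 to 14.23. The software and method of background correction, normalization and summarization are not given in the sources used here. Array medians between 5.10 and 5.27 show that the arrays had been brought to a common level, and the values were used as deposited. All value columns matched a labelled sample. No genome build was named with the table, so no positions are printed, and a gene table of the GRCm38.p6 assembly served only for names, chromosomes and the order of neighbouring genes.

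Probe sets were named from the platform's annotation table, in which 30604 had exactly 1 gene symbol and 2146 several, while 33185 transcript clusters were not listed. Symbols were brought up to date through their gene identifiers for 827 probe sets. Probe sets with exactly 1 symbol were kept if they lay above the median of all transcript clusters of their array (the 50th percentile) on at least 5 arrays, the size of the smallest group, which left 19219. For each gene the probe set with the highest mean over all arrays was used, which gave 19050 genes. Probe sets without a single name were tested separately. Genes without such a probe set were not tested.

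The model in limma 3.58.1 (R 4.3.3) held the 4 group means over all 22 arrays, so that every comparison shared 1 estimate of the spread (18 residual and 4.34 prior degrees of freedom, default eBayes). The 6 comparisons were knockout minus control in males, in females and averaged over the sexes, male minus female in controls and in knockouts, and the male minus the female effect of Sox9 loss. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, with the moderated two-sided test of limma. Littermate controls were used, but the labels tie no array to a litter, and no batch or scan date was available, so no covariate was fitted. Sox9 and Shh were also tested by two-sided exact permutation of the arrays of each sex.

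Before the data were examined, 35 gene lists with 574 entries were fixed for pathways, cell types that the tissue or its dissection could hold, stress, and sex-linked genes, and 461 entries were tested. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. Members were also adjusted over the list alone. The genes named in the text follow a rule fixed at the same time: Sox9 and Shh, the 8 largest higher and the 8 largest lower log2 fold changes among called genes without predicted genes, Riken clones and RNA models, up to 4 members of smallest p of each list described together with the members a count of 5 or fewer refers to, and Xist and the Y-linked genes for the sexes. Genes named outside this rule are said to be so where they appear.

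Alternatives were quantile normalization, median centring of each array, no filter on dim probe sets, a stricter filter at the 75th percentile, the mean of a gene's probe sets, eBayes with trend and robust options, only the arrays of the groups compared, the replicate number as a block, array weights, the mean of the mesenchyme or of the urothelium list as a covariate, leaving out each array in turn, other thresholds for the overlap, and splits of the controls into 2 parts. Each comparison was repeated on 100 splits of its arrays. The programs were tested on simulated data in which 200 genes of known size were changed, 50 per size. In the male comparison 54% of changes of 0.3, 96% of 0.5, 98% of 0.8 and 100% of 1.2 on the log2 scale were called with 11 false calls, and in the female comparison 58%, 90%, 98% and 98% with 6 false calls. In the comparison of control sexes the shares were 60%, 92%, 100% and 100% with 12 false calls. The adjusted threshold is easier to reach with 200 changed genes than with the 38 male and 6 female calls made here after Sox9 loss. The male and female shares may therefore be too high for the real data. A simulated list that was shifted was called with no other list in each of these 3 comparisons. The simulated genes varied independently, so this could not test for false list calls that arise from correlated genes. On the deposited values 93 of 100 splits of the male arrays called at least 1 list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.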

Results

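Gene expression was measured in the epithelium of the urogenital sinus, the fetal tissue from which prostatic buds grow in males, at embryonic day E16.75. The tissue came from C57BL/6J mouse fetuses of both sexes. Knockouts carried Cre recombinase at 1 Shh allele and floxed alleles at both copies of Sox9 (ShhCre/+; Sox9fl/fl). Littermate controls had no Cre and 1 floxed Sox9 allele (Shh+/+; Sox9+/fl). The 22 arrays fell into 6 male controls, 6 male knockouts, 5 female controls and 5 female knockouts. The labels call the replicates biological but do not say whether each array held 1 fetus or a pool, so p-values measured the spread between these arrays. Whole-transcript arrays gave log2 values from 1.59 to 14.23, with array medians between 5.10 and 5.27, and 19050 genes passed the filter on dim probe sets. A set of 23 background control probe sets had a median of 3.19. The number of arrays limits the precision: the median standard error of a log2 fold change after Sox9 loss was 0.065 in males and 0.071 in females.

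Sox9, a transcription factor of the HMG-box family and the deleted gene, was lower in the knockouts of both sexes. It fell from 9.33 ± 0.21 (SD, n = 6) in male controls to 8.26 ± 0.14 (n = 6) in male knockouts, a log2 fold change of -1.07 (SE 0.08, adjusted p = 1.04e-07) and a 2.10-fold decrease. In females it fell from 8.89 ± 0.11 (n = 5) to 7.89 ± 0.09 (n = 5) (SE of the log2 fold change 0.09, adjusted p = 2.28e-06). Every male knockout (8.37 at most) lay below every male control (9.05 at least), and every female knockout (7.99 at most) below every female control (8.77 at least). Two-sided exact permutation tests gave p = 0.00216 over 924 regroupings in males and p = 0.00794 over 252 in females, the smallest values these designs allow. Sox9 stayed above the array medians in all knockout arrays. Where its single probe set lies relative to the floxed part of the gene was not analysed here.

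Shh, the secreted hedgehog ligand of this epithelium and the locus of the Cre insertion, also fell in both sexes. The male values were 11.22 ± 0.12 in controls and 10.77 ± 0.06 in knockouts (log2 fold change -0.45, SE 0.08, adjusted p = 0.00874), and the female values 10.76 ± 0.23 and 10.20 ± 0.14 (log2 fold change -0.56, SE 0.09, adjusted p = 0.0128). Knockout and control arrays did not overlap in either sex, with the same exact permutation p-values as Sox9. Because all knockouts and no controls had Cre at 1 Shh allele, the fall of Shh cannot be assigned to Sox9 loss or to the inserted allele by this design. The female call for Shh was lost without female control 3 (log2 fold change -0.51) or 5 (-0.53), or without female knockout 1 (-0.52) or 4 (-0.56). Neither gene's change differed detectably between the sexes: the male minus female difference was -0.07 for Sox9 (SE 0.12, adjusted p = 0.997) and 0.11 for Shh (SE 0.12, adjusted p = 0.997).

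**Figure D1:**
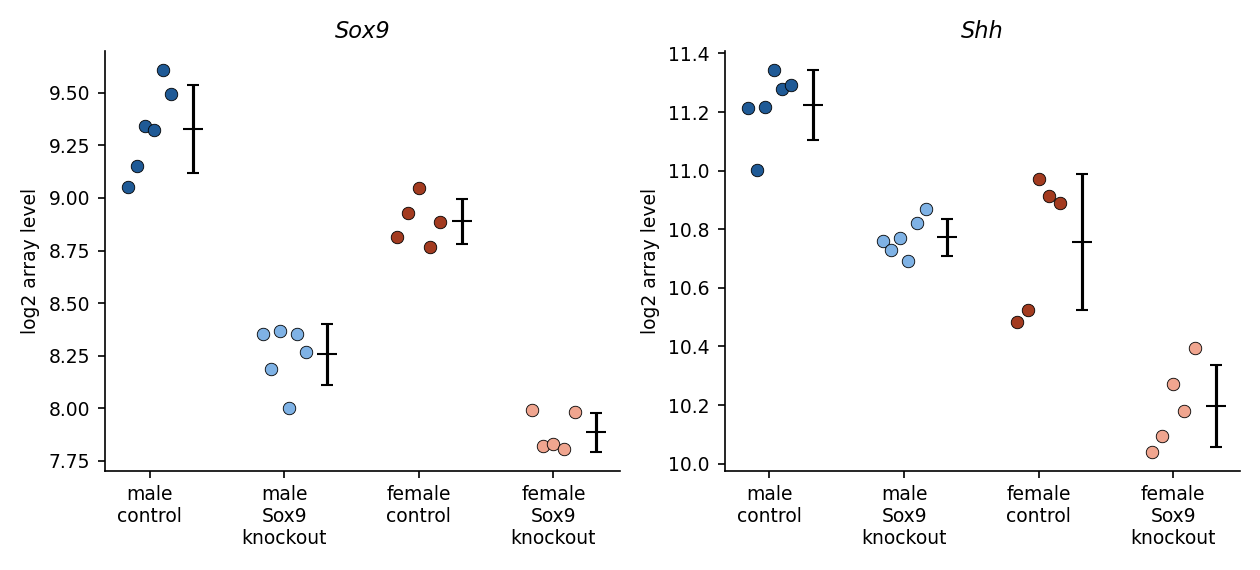
Deposited log2 values of Sox9 and Shh on each of the 22 arrays by group, where each point is 1 array and the bars give the mean ± SD. Knockout and control arrays do not overlap within a sex, and mean Sox9 is 8.26 in male and 7.89 in female knockouts against 9.33 and 8.89 in controls.

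The sex labels were checked on the Y-linked genes Eif2s3y, Kdm5d and Uty and on Xist, the noncoding RNA of the inactive X chromosome. Male arrays had Y-linked means between 7.06 and 7.42 and female arrays between 4.44 and 4.58, and Xist read 4.2 to 4.6 in males and 11.6 to 11.9 in females. All 22 arrays matched their labelled sex. Arrays of 1 group correlated at r = 0.985 to 0.995 across genes (50 pairs), against 0.981 to 0.995 between groups (181 pairs). No pair of arrays had more than 0.0334% of transcript clusters with exactly equal deposited values, so none was counted as deposited more than once. The first principal component held 27.3% of the variance, and sex explained 97.0% of it and genotype 0.00168%. One array stood apart in stromal genes: male control 6 had a mean of 7.37 over 14 mesenchyme genes, against 6.52 to 6.75 in the other male controls, and 7.18 over 11 smooth muscle genes, against 6.25 to 6.40. Of 25 such genes, 19 were higher there than in every other male control, and over all 25 the median difference from the mean of the others was 0.60, with Col1a1 at 8.97 and Col3a1 at 8.20. Dissection had removed the mesenchyme, per the labels.

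**Figure D2:**
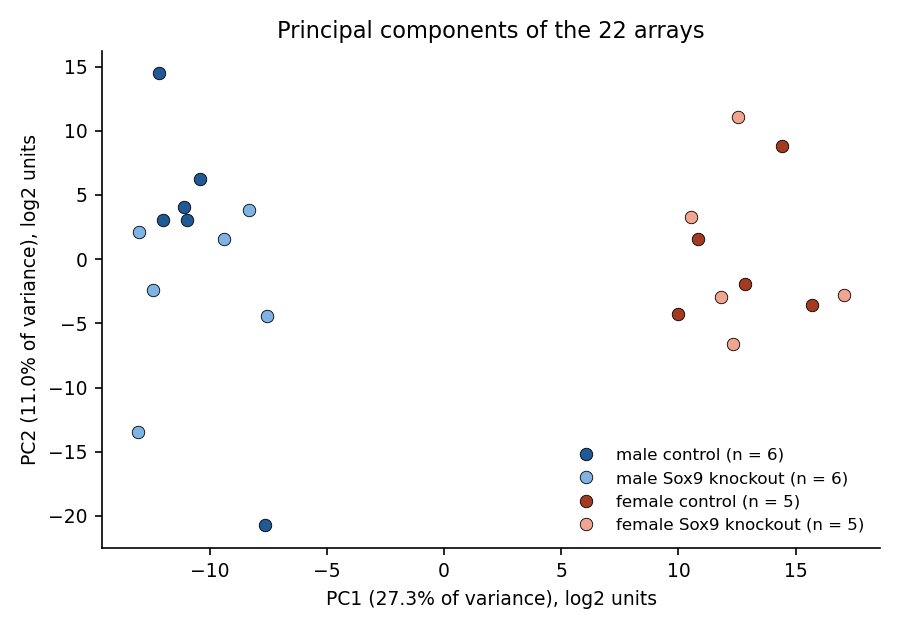
Scores of the 22 arrays on the first principal component (27.3% of the variance) and the second (11.0%), coloured by group, over all genes tested. Males and females separate on the first component, knockouts and controls do not, and on the second male control 4 lies at -20.7 and male control 6 at 14.5.

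The comparison of male knockouts with male controls asks which genes change with the knockout genotype while prostatic buds form. As for Shh, a change of any gene other than Sox9 cannot be assigned by this design to Sox9 loss, the Cre allele or the lower Shh level. In this text, Sox9 loss stands for the difference between these genotypes. The largest fall was that of Cxcr4, the receptor of the chemokine Cxcl12, from 8.63 ± 0.48 to 6.87 ± 0.38 (n = 6 each), or 3.39-fold (log2 fold change -1.76, SE 0.22, adjusted p = 0.000286). Col14a1, a fibril-associated collagen, fell from 7.16 ± 0.53 to 5.91 ± 0.21 (adjusted p = 0.00127), and Mia, a small secreted protein also made by cartilage, from 7.31 ± 0.36 to 6.10 ± 0.17 (adjusted p = 0.000801). Acsm3, a mitochondrial acyl-CoA synthetase, fell by 0.90 (SE 0.12). Itgb8, an integrin subunit that activates latent TGF-beta, and Adamts9, a secreted protease of versican, each fell by 0.80 (SE 0.10 and 0.14). Peg10, an imprinted gene derived from a retrotransposon, fell by 0.83 (SE 0.14). The genes that rose were fewer: Lrrc7, a scaffold protein (0.70, SE 0.13), Ptgdr, a prostaglandin D2 receptor (0.62, SE 0.11), Bmp3, a BMP family ligand (0.51, SE 0.09), and Neto2, an auxiliary subunit of kainate receptors (0.49, SE 0.09).

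In all, 38 of 19050 genes passed an adjusted p of 0.05 in males, 4 higher and 34 lower, and 4 of these changed at least 2-fold. Over all genes, the knockout and control arrays did not overlap for 80 of 19050 (0.420%), a separation that chance gives for 0.216%. An unadjusted p under 0.05 was reached by 1195 genes where 952.5 are expected by chance. Without male control 6, the array with the raised stromal genes, 27 genes passed, and the log2 fold changes were -1.05 for Col14a1, -1.09 for Mia, -0.69 for Peg10 and -0.70 for Adamts9. All 13 named calls passed whichever male array was left out, but with only the male arrays in the model 20 genes passed and Lrrc7, Ptgdr, Neto2 and Peg10 lost their calls, and with array weights Shh lost its call.

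Gene lists fixed for this tissue mostly did not move in males. The retinoic acid list was lower: 0 of its 14 measured genes passed on its own over all genes and 1 was lower when adjusted over the list alone, but the list as a whole had a mean log2 fold change of -0.11 (camera adjusted p = 0.00405, and 0.0236 with an estimated correlation). Its members of smallest p were Aldh1a1 (-0.39, SE 0.10), Rdh10 (-0.33), Aldh1a2 (-0.33) and Rarb (-0.11), the first 3 being enzymes of retinoic acid synthesis and the last a receptor. The hedgehog list (14 genes, mean -0.06, camera adjusted p = 0.0575) had 1 lower gene, Shh, and 2 lower when adjusted over the list alone. Among 15 genes of SOX9-dependent epithelial progenitors, Mia alone fell, over all genes and over the list alone (camera adjusted p = 0.0575). None of 16 cartilage targets of SOX9 changed over all genes and 1, Col2a1 (-0.24), was lower over the list alone. That list's mean (0.00) and median (0.03) were not negative while its test, which was not passed, pointed down (camera adjusted p = 0.775).

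The remaining developmental lists held few or no male calls. Of 18 prostate bud genes Shh fell and none rose, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.621). Of 27 androgen-responsive genes 0 passed, with 1 higher and 1 lower over the list alone (camera adjusted p = 0.775), and of 21 WNT ligands and targets 0 passed by either count (camera adjusted p = 0.954). Bmp3 was the single gene that rose among 22 BMP and TGF-beta genes, and the list alone gave 1 higher and 1 lower (camera adjusted p = 0.596). The 16 other SOX genes gave 0 calls by either count (camera adjusted p = 0.621), and so did the mesenchyme (camera adjusted p = 0.158) and smooth muscle lists (camera adjusted p = 0.22), which were raised in male control 6. In camera, 1 of 35 lists was called in males, but 93 of 100 splits of the male arrays called at least 1 list and up to 13. These splits count any list at the preset correlation and did not test the retinoic acid list itself, which was also called by fry (adjusted p = 0.0278) and kept its camera call whichever male array was left out.

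In females the comparison of knockouts with controls asks the same question in the sex that normally forms no prostate. Besides Sox9 and Shh, 4 genes fell. Acsm3 went from 6.69 ± 0.26 to 5.93 ± 0.31 (n = 5 each; log2 fold change -0.76, SE 0.14, adjusted p = 0.0422), Myo3a, a class III myosin, from 5.85 ± 0.20 to 5.22 ± 0.11 (-0.63, SE 0.08, adjusted p = 0.000663), and Pcsk6, a proprotein convertase, from 7.10 ± 0.09 to 6.73 ± 0.11 (-0.37, SE 0.06, adjusted p = 0.0343). Gpr157, an orphan G protein-coupled receptor, went from 7.70 ± 0.08 to 7.43 ± 0.04 (-0.26, SE 0.05, adjusted p = 0.0343).

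These 6 genes were all the female calls, 0 higher and 6 lower, beside 1041 genes at an unadjusted p under 0.05 and 952.5 expected. Over all genes, the knockout and control arrays did not overlap for 265 of 19050 (1.39%), where chance gives 0.794%. The count dropped to 2 without female control 3, female control 5 or female knockout 4, and to 3 without female control 1, female knockout 1 or female knockout 3. With only the female arrays in the model 3 genes passed, and of these 6 genes all but Sox9 lost their calls. Acsm3 also lost its call with quantile normalization, without the dim filter or with the mesenchyme covariate, and Pcsk6 with quantile normalization. In the model of all groups Myo3a and Sox9 passed whichever female array was left out, while the calls for Acsm3 and Pcsk6 were each lost without any of 8 of the 10 arrays and that for Gpr157 without any of 9. Acsm3 kept its call without female control 2 or female knockout 1, Pcsk6 without female control 4 or female knockout 2, and Gpr157 without female control 4.

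Among the lists, the mean change of 12 urothelial genes in female knockouts was 0.18 (camera adjusted p = 0.00651; adjusted p = 0.708 with an estimated correlation). None passed on its own, over all genes or adjusted over the list alone, and the members of smallest p were uroplakins, the surface proteins of bladder epithelium: Upk3b (0.47), Upk2 (0.40), Upk1a (0.21) and Upk1b (0.14). The hedgehog list had a mean of -0.08, with Shh the 1 call by either count (camera adjusted p = 0.0249, and adjusted p = 0.432 with an estimated correlation), and the receptors Smo and Boc at -0.13 and -0.15. The immune list had a mean of 0.11, with 0 of 12 called by either count (camera adjusted p = 0.0259, and adjusted p = 0.432 with an estimated correlation), among them Tyrobp (0.26) and the complement genes C1qc (0.18) and C1qb (0.19). The squamous list, with 0 of 14 called by either count, had a mean of -0.10 and Krt1 at -0.38 (camera adjusted p = 0.0423, and adjusted p = 0.432 with an estimated correlation). All 4 list calls were lost without female knockout 1, where the urothelial mean was 0.11 and the immune mean 0.07, and the urothelial mean was 0.28 without female knockout 2. Of the female arrays' splits, 31 of 100 called at least as many lists. The hedgehog and immune calls were lost without female knockout 4 as well, the immune call without female control 2 or 4, and the squamous call without any of 6 arrays.

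Averaging the male and female effects gives each gene the weight of all 22 arrays. Bmp3 rose by 0.44 (SE 0.06, adjusted p = 0.000638), Gria3, an AMPA receptor subunit, by 0.43 (SE 0.08), Pdzrn3, a ubiquitin ligase, by 0.41 (SE 0.07) and Ptger3, a prostaglandin E2 receptor, by 0.37 (SE 0.07). Hoxd12 and Abhd1 each rose by 0.34 (SE 0.06), and Neto2 rose by 0.33 (SE 0.06). Cxcr4 fell by 1.25 (SE 0.16, adjusted p = 0.000203), Col14a1 by 0.95 (SE 0.14), Acsm3 by 0.83 (SE 0.09, adjusted p = 6.3e-05), Mia by 0.77 (SE 0.12), Itgb8 and Adamts9 by 0.59 (SE 0.07 and 0.10) and Peg10 by 0.58 (SE 0.10). Sox9 fell by 1.04 (adjusted p = 4.6e-10) and Shh by 0.51 (adjusted p = 9.43e-05).

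On this average 47 genes passed, 9 higher and 38 lower, against 1369 genes at an unadjusted p under 0.05, and without male control 6 the count was 43. P2rx2, an ATP-gated channel, was also called (0.19, SE 0.04, adjusted p = 0.0465) but lost its call without any of 19 of the 22 arrays and under several other settings, quantile normalization among them. Of 13 posterior HOX genes 1, Hoxd12, passed over all genes and 4 were higher when adjusted over the list alone, with Hoxd10 at 0.22, Hoxd11 at 0.17 and Hoxd13 at 0.19 (camera adjusted p = 0.0714). The 5 list calls by camera were all lost with an estimated correlation, and 35 of 100 splits called as many lists. Hedgehog genes had a mean of -0.07 with Shh as the 1 call and 2 lower over the list alone (adjusted p = 0.00411, and adjusted p = 0.113 with an estimated correlation), with Smo at -0.13 and Ihh at -0.18. Retinoic acid genes had a mean of -0.06, with 0 called and 1 lower over the list alone (adjusted p = 0.0291, and adjusted p = 0.113 with an estimated correlation). Basement membrane genes had a mean of -0.05, with 0 called and 1 higher and 1 lower over the list alone (adjusted p = 0.0291, and adjusted p = 0.592 with an estimated correlation). Urothelial genes had a mean of 0.08, with 0 called and 3 higher and 1 lower over the list alone (adjusted p = 0.0418, and adjusted p = 0.734 with an estimated correlation), and basal epithelial genes a mean of -0.04, with 0 called and 2 lower over the list alone (adjusted p = 0.0455, and adjusted p = 0.691 with an estimated correlation). Without male control 6 the lists called numbered 1, and the means were -0.02 for basement membrane and -0.02 for basal epithelial genes. The basal mean was -0.03 without male knockout 4, and the urothelial mean was 0.05 without male control 1 or female knockout 1 and 0.13 without female knockout 2.

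Sox9, Shh, Acsm3 and Pcsk6 were called as lower in both sexes, where 0.0107 shared falls are expected of independent lists. Sox9 is the deleted gene and Shh the locus of the Cre insertion, so their shared fall is no evidence of a shared response. With only the female arrays in the model, Shh, Acsm3 and Pcsk6 lost their female calls. Of the 38 genes called in males, 37 had the same sign in females and 24 of those had an unadjusted p under 0.05 there. Without Sox9 and Shh, 35 of 36 had the same sign, against 52.7% of all genes. The median size of the 38 changes was 0.52 in males, where they were selected, and 0.29 in females. Across all genes the male and female log2 fold changes correlated at r = 0.150, within the range of -0.42 to 0.39 given by 100 relabellings of the arrays, 13 of which were as high. Genes are not independent replicates. The male and female comparisons share no arrays, but their calls rest on 1 shared estimate of the spread.

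Whether the effect of Sox9 loss differed between the sexes was tested as the male minus the female change. Gpr157 was the 1 gene called among 19050: it was 0.14 higher in male and 0.26 lower in female knockouts, a difference of 0.40 (SE 0.06, adjusted p = 0.0292). The call was lost without any of 15 of the 22 arrays, and with quantile normalization, without the dim filter or with trend and robust options. The difference for Myo3a (0.63, SE 0.11, adjusted p = 0.0645) did not pass, and in males Myo3a read 4.53 and 4.54, below the array medians. The larger male than female falls of Cxcr4 (-1.76 and -0.75) and Mia (-1.21 and -0.32) did not pass as a difference either (these 3 genes were chosen here after their values were seen). An unadjusted p under 0.05 was reached by 769 genes, fewer than the 952.5 expected by chance. Immune genes had a mean difference of -0.13 and hypoxia genes one of 0.12, with 0 members called by either count (camera adjusted p = 0.0426 for both). The estimated correlation ended both calls (adjusted p = 0.923 for immune and adjusted p = 0.98 for hypoxia genes), and 72 of 100 splits called at least 2 lists. The hypoxia mean was 0.08 without female control 1 and 0.19 without female control 3.

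**Figure D3:**
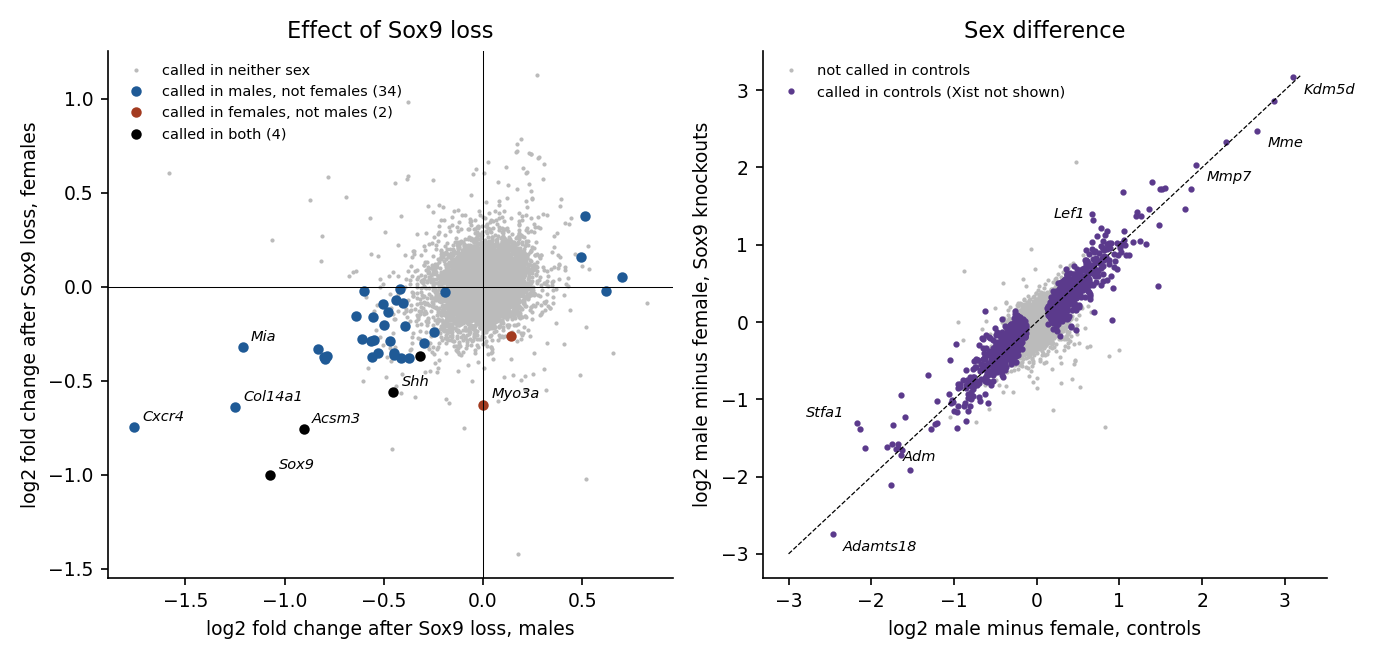
Left, log2 fold change after Sox9 loss in males (horizontal) against females (vertical) for each gene, with coloured points for the 34 genes called in males alone, 2 in females alone and 4 in both. Right, male minus female log2 difference in controls against knockouts, without Xist, with the dashed line marking equal values: genes called in controls correlate at r = 0.959.

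The comparison of male with female controls asks what distinguishes the epithelium that forms prostatic buds. Beyond the Y-linked genes, Mme, a membrane peptidase also called neprilysin, was the autosomal gene with the largest male excess, at 8.45 ± 0.39 (n = 6) against 5.79 ± 0.34 (n = 5), a log2 difference of 2.67 (SE 0.16, adjusted p = 1.44e-10). Mmp7, or matrilysin, was higher by 1.93 (SE 0.21), Sbspon, a secreted matrix protein, by 1.86 (SE 0.16), AU022754 by 1.79 (SE 0.15) and Rgs2, a regulator of G protein signalling, by 1.55 (SE 0.11). Adamts18, a secreted metalloprotease, had the largest female excess among autosomal genes, at 10.46 ± 0.20 against 7.99 ± 0.26 in males (-2.47, SE 0.15, adjusted p = 2.05e-10). Female values were also higher for the stefin A family members Cstdc6 (-2.17, SE 0.16) and Stfa1 (-2.13, SE 0.18), for Gad2, a glutamate decarboxylase (-1.81, SE 0.12), for the lipase-related Pnliprp1 (-1.76, SE 0.13), for Adm, the vasodilator peptide adrenomedullin (-1.75, SE 0.24), and for the chemokine Cxcl13 (-1.73, SE 0.24). Sox9 and Shh were both higher in male than in female controls, by 0.44 (SE 0.09, adjusted p = 0.00159) and 0.47 (SE 0.08, adjusted p = 0.000722).

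Of 19050 genes, 1322 differed between male and female controls, 623 higher and 699 lower in males, and 57 of them by at least 2-fold (30 higher, 27 lower). Over all genes, the arrays of the sexes did not overlap for 1075 of 19050 (5.64%), where chance gives 0.433%. Without male control 6, 1199 genes passed. On the X chromosome 50 of 863 genes were called (5.79%; 14 higher in males and 36 in females), close to the 7.01% of autosomal genes (1264 of 18021; Fisher's exact test, two-sided p = 0.193). Of 5 genes that escape X inactivation, Xist (-7.31), Kdm6a (-0.60), Eif2s3x (-0.40) and Kdm5c (-0.34) were higher in females by either count, and the 3 measured Y-linked genes, Kdm5d (3.10), Uty (2.86) and Eif2s3y (2.28), were higher in males by either count (camera adjusted p = 2.99e-12 and 3.36e-23). These 2 lists were the calls that held with an estimated correlation (adjusted p = 6.53e-05 and 1.59e-05).

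Among 27 androgen-responsive genes, 6 were higher and 2 lower in male controls, and 8 and 3 when adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.114 with an estimated correlation). Mme led them, followed by Hpgd, which degrades prostaglandins (1.36, SE 0.11). The other 4 higher genes, named here after their values were seen, were the kinase Sgk1 (7.32 in male and 6.12 in female controls), the zinc finger factor Zbtb16 (0.80, SE 0.11), the FK506-binding protein Fkbp5 (0.46) and the transporter Abcc4 (0.40). Pmepa1 (-0.93, SE 0.06) and Ndrg1 (-1.60, SE 0.14), known androgen targets in prostate, were lower in males. Of 21 WNT ligands and beta-catenin targets 6 were higher and 2 lower, and 8 and 2 over the list alone (camera adjusted p = 0.00421, and adjusted p = 0.21 with an estimated correlation). They included the target and feedback inhibitor Axin2 (0.58, SE 0.07), the transcription factor Lef1 (0.85, SE 0.14) and the ligand Wnt4 (0.39, SE 0.06), with the secreted inhibitor Sfrp1 (-0.50, SE 0.12) and the ligand Wnt3 (-0.22) lower. Genes of SOX9-dependent epithelial progenitors were higher in males for 5 of 15, none being lower, and for 6 with 1 lower over the list alone (camera adjusted p = 0.00254, and adjusted p = 0.114 with an estimated correlation): Mia (0.92), Etv5 (0.62), Bmp4 (0.44), Id2 (0.43) and Ret (0.36).

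Female controls had higher levels of hypoxia and glycolysis genes, with 10 of 15 called, 0 of them higher in males, and 13 when adjusted over the list alone (mean -0.53, median -0.32, camera adjusted p = 1.2e-12, and adjusted p = 0.0806 with an estimated correlation). Ndrg1 and Adm led the list, and the glucose transporter Slc2a1 (-0.63) and the mitophagy receptor Bnip3 (-0.59) followed. The dissociation stress list had a mean of -0.21 with 2 of 16 lower by either count, Jun (-1.04) and Btg2 (-0.29) (camera adjusted p = 0.00501, and adjusted p = 0.352 with an estimated correlation). The proliferation list had a median of 0.19, with 4 of 22 called, all higher in males, and 12 over the list alone (camera adjusted p = 3.43e-08, and adjusted p = 0.265 with an estimated correlation). The 4 genes were Cdc20 (0.32), Bub1 (0.28), Top2a (0.28) and Aurkb (0.24), and each lost its call without any of 6 to 9 of the 11 control arrays, male control 6 among them for all 4, and without the dim filter all 4 lost their calls. Other SOX genes were lower in males for 3 of 16 and over the list alone for 3 with 1 higher: Sox11 (-0.55), Sox7 (-0.63) and Sox4 (-0.25) (camera adjusted p = 0.0205, and adjusted p = 0.247 with an estimated correlation). Hoxd10 (-0.63) and Hoxd11 (-0.43) were lower among 13 posterior HOX genes by either count (camera adjusted p = 0.0387, and adjusted p = 0.352 with an estimated correlation). That list call was lost without male control 2, male control 6, female control 4 or female control 5.

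Of 16 Notch genes 2 were lower in males by either count, Hey1 (-0.53) and Jag1 (-0.27) (camera adjusted p = 0.0334, and adjusted p = 0.265 with an estimated correlation), a call lost without male control 3 or female control 5. Of 14 p53 response genes 4 were lower by either count, led by the cell cycle inhibitor Cdkn1a (-0.70) and with Perp (-0.15), Phlda3 (-0.18) and Bcl2l11 (-0.19) (camera adjusted p = 0.0476, and adjusted p = 0.265 with an estimated correlation), a call lost without male control 2, 4 or 6 or female control 1 or 2. In the BMP and TGF-beta list genes moved both ways, with 5 of 22 higher and 3 lower, and 6 and 4 over the list alone (camera adjusted p = 0.657): Bmp2 was higher by 0.76 and Id3 by 0.37, while the pseudoreceptor Bambi was at -1.20 and the activin antagonist Fst at -0.79. This list's median (0.02) and test pointed up and its mean (-0.02) down. Retinoic acid genes were also mixed, with 2 of 14 higher and 3 lower by either count (camera adjusted p = 0.797), among them Aldh1a1 (0.80) and Stra6 (0.77) against Aldh1a2 (-0.97) and Rara (-0.25). The basement membrane list was mixed as well, with 4 of 18 higher and 3 lower by either count (camera adjusted p = 0.211), among them the laminins Lamc1 (0.59), Lamb2 (0.42) and Lama3 (-0.22). Of 18 prostate bud genes Lef1, Shh and Edaradd (0.33) were higher and Foxa2 (-0.26) lower, and 5 and 1 over the list alone (camera adjusted p = 0.0804). Some of these calls were lost without any 1 of several control arrays: Jag1 and Perp for 3 of 11, Phlda3 and Foxa2 for 5 and Bcl2l11 for 7. With only the control arrays in the model, Perp, Phlda3, Bcl2l11, Foxa2 and the p53 list lost their calls.

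Epithelial and stromal markers showed no list call between the control sexes. In the basal list Krt17 was lower (-0.76) and Pdpn higher (0.51), with 1 of 16 higher and 3 lower, and 3 and 6 over the list alone (camera adjusted p = 0.797). Psca, a surface protein of prostate and urothelium, was higher (0.82) in the luminal list, with 2 of 16 higher and 1 lower, and 6 and 2 over the list alone (camera adjusted p = 0.0542). Spink5, a protease inhibitor, was higher (1.48) and Krtdap lower (-1.01) among 14 squamous genes, with 1 higher and 3 lower, and 1 and 4 over the list alone (camera adjusted p = 0.246). Dcn, or decorin, was the 1 of 14 mesenchyme genes called by either count, and it was lower in males (-0.36; camera adjusted p = 0.308) with a call lost without any of 7 of the 11 arrays, while 0 of 11 smooth muscle genes were called by either count (camera adjusted p = 0.467). In all, 12 of 35 lists were called in controls, a number that 1 other of 100 splits of the control arrays also reached.

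**Figure D4:**
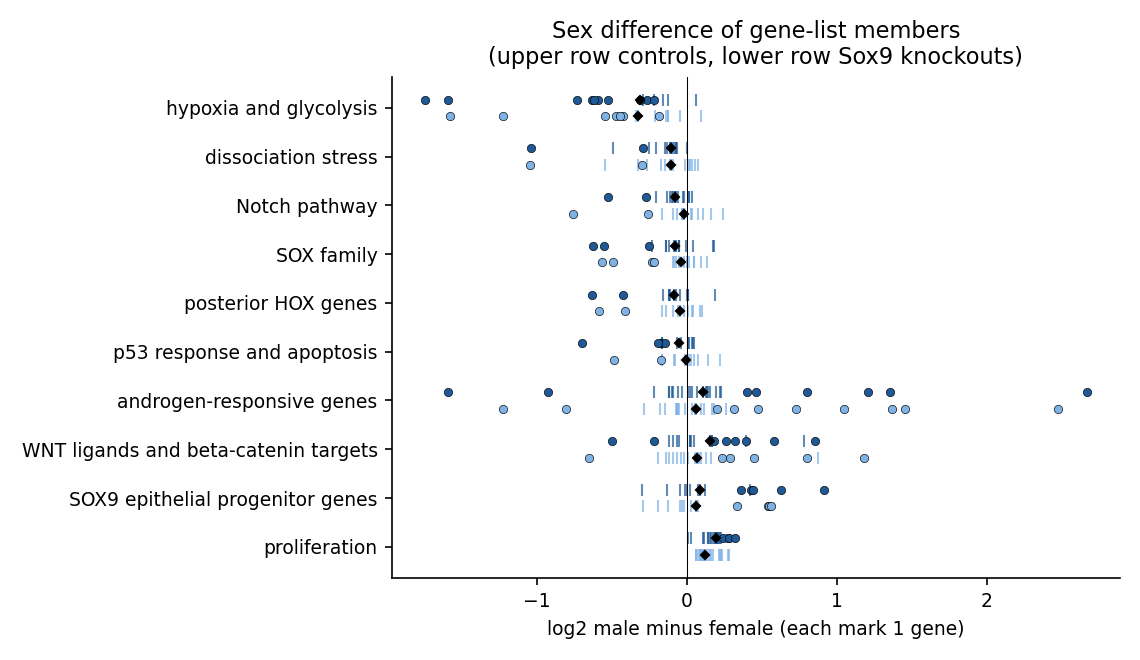
Male minus female log2 difference of each measured gene of 10 fixed lists, controls in the upper and knockouts in the lower line of each list, where filled circles are genes called at an adjusted p of 0.05, ticks are the other genes and the black diamond is the list's median. The hypoxia list lies below 0 in both genotypes, with 10 of 15 genes called in controls and 7 in knockouts.

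The comparison of male with female knockouts asks the same of the knockout epithelium, where Sox9 was lower but stayed above the array medians. Mme was higher in males by 2.48 (SE 0.16), Mmp7 by 2.04 (SE 0.21), the adhesion molecule Ceacam1 by 1.81 (SE 0.15), Rgs2 by 1.73 (SE 0.11) and the actin-binding Coro2a by 1.72 (SE 0.09). Adamts18 (-2.74, SE 0.15), Pnliprp1 (-2.11, SE 0.13), the synaptic protein Unc13c (-1.92, SE 0.15), the kinase Nuak1 (-1.72, SE 0.15), the oxytocin receptor Oxtr (-1.65, SE 0.20), the netrin receptor Dcc (-1.62, SE 0.17) and Gad2 (-1.61, SE 0.12) were higher in females. Shh kept a male excess of 0.58 (adjusted p = 5.99e-05) and Sox9 one of 0.37 (adjusted p = 0.00703). Xist differed by -7.46, and Kdm5d, Uty and Eif2s3y by 3.17, 2.85 and 2.33.

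In the knockouts 1369 genes were called between the sexes, 698 higher and 671 lower in males, 73 of them by at least 2-fold. Over all genes the arrays did not overlap for 1108 (5.82%), where chance gives 0.433%. Of the genes called in either genotype 810 were called in both, and 809 of them had the same sign, where independent lists share 47.4 genes of the same sign. Across all genes the sex differences of controls and knockouts, which share no arrays, correlated at r = 0.770, and 1295 of the 1322 genes called in controls kept their sign in knockouts. The median of these genes' difference in knockouts was 84.7% of that in controls (quartiles 59.4% to 109%). The genes were selected on the control difference that also serves as the divisor, which lowers this share. When genes were selected in 3 against 3 control arrays and compared with the other controls, 3 male and 2 female, the summed difference in knockouts was 104% of that in those controls (96.4% to 113% over 50 splits).

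The list calls in knockouts were 6 of 35, with up to 9 in other splits of the same arrays and 22 of 100 splits as high. The X-escape list (4 lower by either count, adjusted p = 1.16e-12) and the Y-linked list (3 higher by either count, adjusted p = 8.57e-25) held with an estimated correlation (adjusted p = 4.76e-05 and 9.96e-06). Hypoxia genes were higher in females for 7 of 15 and over the list alone for 11 (mean -0.41, adjusted p = 1.84e-08, and adjusted p = 0.214 with an estimated correlation), with Adm at -1.58 and Ndrg1 at -1.23. Androgen-responsive genes were higher in males for 8 of 27 and lower for 2, and for 10 and 3 over the list alone (adjusted p = 0.00372, and adjusted p = 0.0632 with an estimated correlation), with Hpgd at 1.46 and Sgk1 at 1.37. WNT genes were higher for 5 of 21 and lower for 1, and for 6 and 1 over the list alone (adjusted p = 0.0129, and adjusted p = 0.386 with an estimated correlation), with Axin2 at 0.80 and Lef1 at 1.18. Of 22 proliferation genes 0 were called over all genes and 3 higher over the list alone, with Rrm2 at 0.27 and Mcm4 at 0.28 (adjusted p = 3.46e-06, and adjusted p = 0.503 with an estimated correlation). Mia differed between the sexes by 0.92 in controls and 0.03 in knockouts, a change that did not pass the test of the difference.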

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

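The tests of genes beside Shh and Sox9, of 5 against 5 male arrays and of the mesenchyme mean as a covariate were chosen only after the result was seen. All other tests in this part were set before.

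Of the 100 tested genes nearest to Shh, 50 on either side, 3 were called on the average of the sexes: 9530036O11Rik, the gene next to Shh, at -0.25, Nupl2 at -0.23 and Abhd1 at 0.34. In all 7 had an unadjusted p under 0.01, against 411 of 18695 other genes (odds ratio 3.35, 95% interval 1.30 to 7.24), but the 3 calls prompted the test, and with called genes left out 4 of 97 stood against 369 of 18653 (odds ratio 2.13, 0.566 to 5.69, one-sided Fisher's exact p = 0.128). Whether a local effect of the Cre allele, or of DNA linked to it, reaches these genes therefore stays open. Around Sox9, with 0 calls by limma, the share was 5 of 100 (odds ratio 2.34, 0.739 to 5.70, one-sided Fisher's exact p = 0.0712, and p = 0.0499 with called genes left out of the others, as was done for Shh). These versions of the test fall on either side of 0.05, so with so few genes a local effect of the floxed alleles stays open. A response of these neighbours to Sox9 loss itself stays open as well, since every knockout carried both alleles.

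More genes were called after Sox9 loss in males (38) than in females (6). The larger male groups do not account for all of it, since 5 against 5 male arrays called a median of 29.5 genes (17 to 49 over the 36 ways), and neither does a larger spread of the female arrays, whose median residual SD was 0.868 times that of the males (0.102 against 0.118). A smaller effect in females stays open: the 30 genes of smallest p in 3 against 3 male arrays had a mean effect of 0.38 in the male arrays left out and 0.20 in females (medians over 100 splits), a ratio of 54.3%, but the ratio was under 50% in 41 of 100 splits and at least 75% in 3. The male count was 27 without male control 6, the array with raised stromal genes, and of 19050 genes only Gpr157 differed between the sexes when the difference itself was tested.

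The hypoxia and glycolysis list had a mean male minus female difference of -0.53 in controls and -0.41 in knockouts, with 10 and 7 of 15 genes called lower in males, and its camera calls were lost with an estimated correlation (adjusted p = 0.0806 and 0.214). A stress of dissection that differed between the sexes may raise such genes, but with the mean of the dissociation stress list as a covariate 101% of the difference was left and 9 of 10 calls in controls, while 533 genes changed their call. With the mesenchyme mean as a covariate 97.5% was left and again 9 calls, while 153 genes changed their call. Each covariate ended the call of Hk2 (log2 difference -0.32, SE 0.09, adjusted p = 0.0409), which went to -0.25 (SE 0.11, adjusted p = 0.201) with a smaller difference and a larger error under the stress mean and to -0.31 (SE 0.10, adjusted p = 0.055) under the mesenchyme mean. A covariate can remove only its slope times its own difference between the sexes. The mesenchyme means of the control arrays covered much the same range (6.52 to 7.37 in males, 6.56 to 6.77 in females), so that covariate could remove little. The 97.5% left therefore does not show whether the hypoxia genes followed the mesenchyme mean. For the stress mean, the share left shows that the list's mean difference did not follow it among the arrays of a group. The covariates' slopes come from differences within groups only. A handling difference between the sexes is therefore not excluded, and the stress list was itself lower in male than in female controls (mean -0.21). A difference that belongs to sex was not tested.

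Repeating each comparison on 100 splits of its own arrays shows where chance can be excluded for the counts of genes, each taken as a whole. Males gave 38 genes against a highest other split of 1, females 6 against 1, the average of the sexes 47 against 4, control sexes 1322 against 2 and knockout sexes 1369 against 10, and in each of these 1 split, the real one, reached the count. The knockout counts include Sox9, the deleted gene, and Shh, the locus of the Cre insertion. In females these 2 alone exceed the highest other split, so the count does not exclude chance for the other 4 female calls. The sex difference in the effect of Sox9 loss gave 1 gene, the highest other split also gave 1, and 3 splits reached it. For lists, the control sexes gave 12 against 12 in the highest other split, and 2 of 100 splits, the real one included, were as high. The 12 include the X-escape and Y-linked lists, which follow from the sex labels and were the 2 that held with an estimated correlation. The low share of splits therefore does not exclude chance for the other lists called. Chance cannot be excluded either for the list counts of males (1 list, highest other 13, 93 splits as high), females (4, highest other 7, 31 splits), the average (5, highest other 11, 35 splits), the knockout sexes (6, highest other 9, 22 splits) or the sex difference in the effect of Sox9 loss (2, highest other 12, 72 splits).

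The effect of Sox9 loss differed between the sexes, by its own test, for Gpr157 (0.40) and in camera for the immune (-0.132) and hypoxia lists (0.125), both lost with an estimated correlation (adjusted p = 0.923 and 0.98). The call for Gpr157 was lost without any of 15 of the 22 arrays. Among 15439 transcript clusters without a single gene name, which no comparison used, 1 was called after Sox9 loss in females, 4 on the average of the sexes, 149 between control sexes and 186 between knockout sexes.

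A single array lay far from the rest of its group in 22 of 320 groups of values tested (array medians, list means and named genes), where chance gives about 1 in 20, or 16. Male control 6 stood out in the means of mesenchyme genes (7.37, others 6.52 to 6.75), smooth muscle genes (7.18, others 6.25 to 6.40) and basal epithelial genes (9.59, others 9.39 to 9.43), and in Col14a1 (8.19, others 6.70 to 7.16) and Mme (9.21, others 8.18 to 8.51). Male control 4 had the highest array median (5.23, others 5.11 to 5.16), SOX family mean (7.48, others 7.31 to 7.36) and cartilage target mean (6.57, others 6.35 to 6.39) of its group. Male control 2 was lowest in androgen-responsive genes (7.62, others 7.66 to 7.68) and WNT genes (7.00, others 7.11 to 7.17), and male control 1 was high in Adamts18 (8.50, others 7.77 to 7.97) and low in Adm (6.85, others 7.84 to 8.42). Among male knockouts, replicate 3 was high in intestinal genes (5.95, others 5.78 to 5.84) and low in Cxcr4 (6.16, others 6.83 to 7.22), replicate 4 was low in Adm (7.58, others 8.04 to 8.30) and high in Nuak1 (8.33, others 7.35 to 7.70), replicate 6 was low in immune genes (5.93, others 6.03 to 6.07) and replicate 1 was high in Ptger3 (7.12, others 6.84 to 6.93). Female knockout 2 was high in mesenchyme genes (6.72, others 6.61 to 6.63) and in Adm (10.35, others 9.36 to 9.62). Among female controls, replicate 5 was high in red blood cell genes (5.63, others 5.35 to 5.42) and replicate 4 was low in Ceacam1 (7.53, others 8.13 to 8.19).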

How the results depend on the processing

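No alternative here was chosen after the results were seen, and 0 results reversed. Of 212 named genes and comparisons, 174 kept the same call under every alternative in which they were tested, each array left out included (181 were tested with the stricter filter, and the average and the difference between the sexes were not run with only the arrays of the groups compared). Sox9 kept its call in both sexes under all alternatives run, with log2 fold changes of -1.13 to -1.02 in males and -1.03 to -0.96 in females when 1 array was left out. Neither quantile normalization nor median centring put the median of all genes over 0.1 from 0. With 5 or 6 arrays per group, simulated changes of 0.3 on the log2 scale were called for 27 of 50 genes in males and 29 of 50 in females, and changes of 0.5 for 48 and 45. Background control probe sets had a median of 3.19, below the array medians that set the filter.

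For values that moved, the cause was not tested unless stated. Genes called for the sex difference in the effect of Sox9 loss went from 1 to 0 with quantile normalization, with no dim filter and with trend and robust options (limma, 769 genes at an unadjusted p under 0.05 as reported), and to 2 with array weights. List calls for that difference (2) went to 1 with median centring, the stricter filter, array weights or the mesenchyme covariate, and to 0 with the urothelium covariate, an estimated correlation or fry. Male list calls (1) went to 3 with no filter or the urothelium covariate, 2 with the stricter filter and 4 with only the male arrays. The urothelium covariate removes the call of its own list by construction. Female list calls (4) went to 1 with the stricter filter, 2 with array weights and 0 with an estimated correlation or fry. List calls on the average of the sexes (5) went to 2 with array weights or the urothelium covariate, 1 with the mesenchyme covariate and 0 with an estimated correlation or fry. The list calls of the control (12) and knockout sexes (6) went to 2 each with an estimated correlation, whereas fry gave 12 and 7. With only the arrays of the groups compared, which leaves fewer arrays to estimate the spread, male genes went from 38 to 20, female genes from 6 to 3 and genes called in both sexes from 4 to 1, and Shh in females (-0.56) lost its call. Array weights gave 11 female genes and 72 on the average, and Shh in males (-0.41) lost its call. At an adjusted p of 0.01 the overlap was 1. The share of the sex difference kept in knockouts was 104% with controls split into 2 parts, against 84.7% unsplit. The first is a ratio of summed differences. The second is a median of ratios whose divisor also selected the genes, which lowers it. How much each of these accounts for was not tested.

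When 1 array was left out, calls ranged from 27 to 49 genes in males, 2 to 6 in females (2 without female control 3 or 5 or female knockout 4, 3 without female control 1 or female knockout 1 or 3), 41 to 56 on the average, 1006 to 1694 between control sexes, 1073 to 1434 between knockout sexes and 0 to 2 for the sex difference in the effect of Sox9 loss. List calls ranged from 1 to 8 in males (1 without male control 4 or 6 or male knockout 4, 2 to 8 without any other male array, 6 without male control 1 and 8 without male control 3), 0 to 6 in females (0 without female knockout 1, 2 without female control 2 or female knockout 4), 1 to 8 on the average (1 without male control 6, male knockout 4 or female control 1, 2 without male control 4 or female knockout 1, 3 without female control 2, 8 without female control 4), 10 to 14 and 6 to 9 between the sexes, and 0 to 3 for that difference. Shh ranged from -0.50 to -0.43 in males and from -0.63 to -0.51 in females, where its call was lost without female control 3 (-0.51) or 5 (-0.53) or female knockout 1 (-0.52) or 4 (-0.56). Named calls lost for at least 1 array were 0 of 13 in males, 4 of 6 in females, 1 of 18 on the average, 18 of 87 and 9 of 89 between control and knockout sexes, and 1 of 1 for that difference.

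The labels do not say whether the replicate numbers pair the arrays, and the values gave little sign of it. Deviations of 31 same-numbered pairs correlated from -0.42 to 0.28, and 4 pairs were over 0.1. Between male and female knockouts, however, every same-numbered pair correlated above 0, from 0.012 to 0.253, so a litter or batch shared by number is not excluded. With the replicate block 30 genes were called in males, 4 in females (the calls of Pcsk6 and Gpr157 ended), 49 on the average, 1045 and 1130 between the sexes, and 2 genes and 0 lists for the sex difference in the effect of Sox9 loss. Between control sexes the block ended the calls of the p53 and posterior HOX lists and, among other genes, of Foxa2, Cdc20, Bub1, Top2a and Phlda3.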

Other observations

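The genes of the paragraphs on sex differences and on Sox9 loss were chosen only after their values were seen, and the test of the last paragraph was set before.

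Some of the sex differences lay in neighbouring genes. Stat5a and Stat5b, adjacent transcription factors of cytokine, growth hormone and prolactin signalling, were both higher in males, Stat5a by 0.97 in controls and 1.02 in knockouts (SE 0.07, adjusted p = 1.46e-09 and 6.21e-10) and Stat5b by 0.61 and 0.73 (SE 0.06, adjusted p = 1.71e-07 and 9.64e-09). The stefin and cystatin genes Stfa1, Cstdc5 and Cstdc6, which lie side by side, were higher in females in controls (-2.13, -1.64 and -2.17) and in knockouts (-1.38, -0.95 and -1.30). Probes of such near-identical copies were not checked for shared sequence, so these 3 values are uncertain as separate measurements. Gad2 (-1.81 and -1.61) and Myo3a (-1.31 and -0.68), with 1 tested gene between them, were also higher in females. The desmosomal cadherin Dsg3 (-1.20 and -1.02), the matrix protein Dpt (-1.67 and -1.58), the netrin receptor Dcc (-1.68 and -1.62) and the oxytocin receptor Oxtr (-1.63 and -1.65) were higher in females, and the tight junction protein Cldn1 (1.02 and 0.90) was higher in males.

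After Sox9 loss in males, both Noxo1 (-0.44, SE 0.08, adjusted p = 0.00705) and Noxa1 (-0.40, SE 0.08, adjusted p = 0.0343) fell, the organizer and activator subunits of the NADPH oxidase Nox1. In females they read -0.07 and -0.09, and the difference between the sexes did not pass for either (adjusted p = 0.997). Peg10 and its neighbour Sgce, imprinted genes expressed from the paternal allele, both fell in males (-0.83 and -0.47, adjusted p = 0.00504 and 0.0436), and on the average of the sexes Sgce fell by 0.38 (SE 0.07). Peg10 lost its male call with only the male arrays in the model. Whether Noxo1, Noxa1 and Sgce keep their calls under the alternatives or with an array left out was not tested. Cxcl12, the ligand of Cxcr4, was at -0.18 in males and did not pass.

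A hypothesis tested was that loss of Sox9 moves the male epithelium toward the female profile, lowering genes with a male excess and raising those with a female excess. Comparing both differences on the same male controls is biased toward that outcome (mean change along the sex direction -0.017), so the male controls were split into 2 groups of 3, 1 to define the sex direction over a median of 696 genes and 1 to measure the change. The median of this mean change was 0.021 over 20 splits (-0.00041 to 0.041), and 81 of 100 relabellings of the male arrays gave a value as low (-0.071 to 0.060). The data did not bear this hypothesis out.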
